A study of Homo sapiens with 18 samples.

How the data were processed

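RNA was measured in HEK-293E cells, a line of human embryonic kidney cells, by RNA sequencing of 18 libraries in 6 groups of 3. Per the labels' protocols, cells were starved overnight in low-serum medium and fed by returning them to regular growth medium. The groups were starved cells, cells fed for 1 h and cells fed for 4 h, each without and with Torin1, an inhibitor of the kinase mTOR. The dose and duration of Torin1 are not given in the sources used here.

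Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and sequenced, and reads were aligned with STAR in a 2-pass procedure. The labels also name RSEM and DESeq2, without versions. They name a C. elegans genome build, whereas the identifiers in the deposited tables are human Ensembl identifiers, so no coordinates are given, and the human build and annotation release are not given in the sources used here. Strand use in counting is not given either, so genes that overlap others on the opposite strand are uncertain, as are members of families with near-identical sequence (metallothioneins, histones, HSPA1B, F8A1, RPS26). The deposited gene table holds expected counts, that is, read counts estimated per gene by RSEM per the labels, and 3.32% of its values were not whole numbers. The deposited isoform table holds estimated counts per transcript as whole numbers. Column sums differed between libraries in both tables, so the values were taken as not normalised.

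The gene table held 60623 genes, of which 29880 had a count above 0 in a library. Symbols were found for 60295 identifiers in a table of gene names and for a further 309 in GENCODE release 29. Of 227368 isoforms, 205950 matched release 29, and these held 98.9% of isoform counts. Library totals ranged from 10510689 to 13690035 counts. A count of 0 in a library allows a level of up to 0.219 to 0.285 CPM (counts scaled to a common library total), taking 3 counts as the limit, which covers counting error only.

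Counts were rounded and genes were kept by filterByExpr with a minimum count of 10, which left 16414 genes. They were scaled by the trimmed mean of M values (TMM) and fitted with edgeR 4.0.16 in R 4.3.3 as 6 group means over all 18 libraries, with robust dispersions and quasi-likelihood F tests. This left 12 residual degrees of freedom and a common biological coefficient of variation of 10.6%. P values were adjusted by the Benjamini-Hochberg method over the genes tested in each comparison, and genes with an adjusted p under 0.05 were called. The comparisons were 1 h and 4 h feeding against starvation, 4 h against 1 h of feeding, Torin1 within each feeding state, feeding under Torin1, and the interaction of feeding with Torin1 at 1 h and at 4 h. The labels do not say whether the replicates were separate cultures, so p values measure the spread between these libraries only.

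The 41 gene lists for signalling, metabolism, translation, stress responses, the cell cycle and markers of other cell types were fixed before the data were examined, as were the design, the alternatives and the rule for naming genes. Lists with at least 5 tested genes were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with an inter-gene correlation preset at 0.01 and adjustment over the lists of a comparison. The same test with an estimated correlation, and fry, which asks whether a list's genes moved on balance in 1 direction, were run as alternatives. Named genes were those with the largest changes in each direction among called genes with a mean of at least 5 CPM and no overlap between the groups compared (not asked of interactions), the members with the smallest p of shifted lists, and 20 genes fixed beforehand. Other named genes are said to be chosen after their values were seen. A mean of CPM is given with its SD over 3 libraries and a log2 fold change with its SE.

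Isoform use was tested with diffSpliceDGE in edgeR on 48663 isoforms of 10700 genes. Alternatives were DESeq2 1.42.0 size factors and its Wald test, limma-voom, other filters, leaving out mitochondrially encoded genes, fitting only the groups compared, replicate number as a block, leaving out each library, and, added after the data were seen, scaling by total counts. For overlaps with shared starved libraries, 20 sets of unchanged groups were simulated. Other splits of the samples were refitted, all 10 for groups of 3 against 3 and 100 drawn for larger designs.

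The tests were tried on simulated counts with the real library sizes and dispersions and, in every group, the means of starved cells. Changed genes of the gene test were drawn from genes outside the lists with at least 1 CPM in starved cells. For 1 h feeding, with 16414 genes, the gene test recovered 56.7%, 70.2% and 93.9% of genes changed 1.5-fold, 2-fold and 4-fold, and called 13 unchanged genes. For 4 h feeding under Torin1 these shares were 55.2%, 82.1% and 90.9%, with 12 unchanged genes called, and for the interaction at 4 h 41.8%, 55.2% and 86.4%, with 4. The isoform test failed: for 4 h feeding, with 9627 genes, it recovered 1 of 100 genes with a 2-fold and 7 of 100 with a 4-fold change in an isoform and called 40 unchanged genes. The limma-voom form recovered 8 and 46 and called 6. Counts of genes from the isoform test are therefore not interpreted.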

Results

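The data covered starved HEK-293E cells and cells fed for 1 h or 4 h, each without and with the mTOR inhibitor Torin1, with 3 libraries per group. Mean depth per group ranged from 11415433 counts (SD 582580, 4 h fed) to 12832760 (SD 549047, 4 h fed with Torin1), and between 14404 and 15714 genes had at least 10 reads in a library. Mitochondrially encoded genes, ribosomal RNA included, held 2.23% of counts (SD 0.356) in starved cells and 3.37% (SD 0.560) in 4 h fed cells. Component 1 of a principal component analysis held 63.3% of the variance. Its scores were between −76.9 and −59.4 in starved and 1 h fed libraries, between −27.2 and −14.3 in 4 h fed libraries and between 47.5 and 57.7 in the libraries with Torin1. Component 2 held 11.7% and set the 4 h fed libraries apart, at −51.3 to −49.7 against 0.83 to 21.4 in the other libraries.

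**Figure D1:**
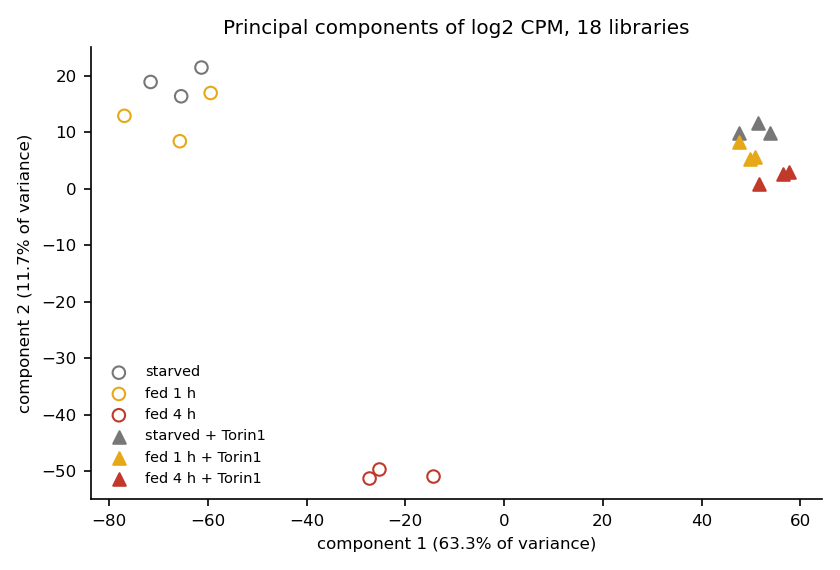
Scores of the 18 libraries on components 1 and 2 of log2 CPM. Circles are libraries without Torin1 and triangles libraries with it.

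The comparison of 1 h of feeding with starvation asked which genes responded early to serum and nutrients. EGR1 (ENSG00000120738), a transcription factor induced by growth factors, rose from 14.8 ± 5.47 to 105 ± 41.9 CPM (SD, n = 3), a log2 fold change of 2.83 (SE 0.34, edgeR adjusted p = 0.00205). FOSB and EGR3, immediate early genes as well, rose by 2.02 (SE 0.31) and 2.01 (SE 0.29), and ID1, a target of BMP signalling, rose by 1.98 (SE 0.22, edgeR adjusted p = 6.69e-06). TXNIP (ENSG00000265972), which restrains glucose uptake, fell from 43.1 ± 5.16 to 15.9 ± 2.94 CPM, a log2 fold change of −1.44 (SE 0.16, edgeR adjusted p = 6.69e-06), and the cell cycle inhibitor CDKN1B fell by 0.60 on the log2 scale (SE 0.11). FOS rose by 1.17 (SE 0.31) but missed the threshold (edgeR adjusted p = 0.103), and the cholesterol synthesis gene HMGCS1 was not called (0.08, SE 0.14).

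At 1 h of feeding, 79 genes were higher and 27 lower among 16414. This count rested on few libraries, since it was 55 without starved replicate 2 and 248 without 1 h fed replicate 1. The 13 mitochondrially encoded genes had a median of 0.43 with 0 called, a camera adjusted p of 6.07e-11 and 0.321 with an estimated correlation. Of 28 immediate early genes, 4 were higher and 24 were not called (7 higher when adjusted over the list alone), with a median log2 fold change of 0.27 and a camera adjusted p of 4.2e-07 that became 0.331 with an estimated correlation. Of 11 replication histones, 2 were higher, among them H1-4 (1.76, SE 0.33) and H4C8 (1.58, SE 0.36), and 9 were not called (4 higher and 1 lower when adjusted over the list alone); the call of H1-4 was lost without starved replicate 3 and that of H4C8 without starved replicate 2 or 3 or 1 h fed replicate 3. Camera called 15 of 38 lists, 7 up and 8 down, and 0 of these held with an estimated correlation, while fry called 1, the replication histones (median 0.48, fry adjusted p = 0.0284).

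After 4 h of feeding, metallothionein genes, which encode proteins that bind zinc and copper, stood far above starved cells, although MT1X had begun to rise by 1 h (2.82, SE 0.36, chosen for that time after its value was seen). MT1X (ENSG00000187193) went from 0.488 ± 0.168 to 74.3 ± 3.75 CPM (SD, n = 3), a log2 fold change of 7.23 (SE 0.27, edgeR adjusted p = 8.93e-19), MT1F rose by 4.82 (SE 0.43) and MT2A by 4.07 (SE 0.17). The ribosome assembly factors WDR75 and MRTO4 rose by 2.09 (SE 0.10) and 1.60 (SE 0.09), and UBTF, which activates transcription of ribosomal DNA, by 1.80 (SE 0.09). XBP1 and HERPUD1, genes of the unfolded protein response of the endoplasmic reticulum, fell by 1.24 (SE 0.09) and 1.29 (SE 0.10) on the log2 scale. MSMO1, a gene of cholesterol synthesis, fell from 145 ± 14.1 to 49.5 ± 1.36 CPM (−1.55, SE 0.14), and HMGCS1 fell by 1.18 (SE 0.14) on the log2 scale.

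Changes of 4 h feeding reached 3801 genes upward and 3139 downward, 1347 and 640 of them by at least 2-fold. With DESeq2 size factors the split was 3470 to 3601. Of 42 ribosome assembly genes, 19 were higher, 5 lower and 18 not called, with the same counts when adjusted over the list alone (camera adjusted p = 0.00255; 0.616 with an estimated correlation). All 13 mitochondrially encoded genes but 1 were higher (median 0.67), including MT-ATP8 (1.01, SE 0.21), with a camera adjusted p of 5.61e-04 that became 0.616 with an estimated correlation. Of 24 cholesterol synthesis genes 1 was higher, 15 were lower and 8 were not called, and of 18 unfolded protein response genes 0 were higher and 10 lower, both unchanged when adjusted over the list alone. FOXO target genes, which are active when growth factors are lacking, were lower in 10 of 22 cases and higher in 2 (10 and 3 when adjusted over the list alone), with CCNG2 at −1.32 (SE 0.10) and HBP1 at −1.23 (SE 0.14). Ribosomal protein genes had a median of −0.18 (−0.22 with DESeq2 size factors and −0.20 with total counts), with 27 of 79 lower, 1 higher and 51 not called (25 and 1 when adjusted over the list alone), and the higher gene was RPS26 (0.60, SE 0.07). Camera called 16 lists, 5 up and 11 down. None held with an estimated correlation (0 lists by camera in limma, against 16 with the preset value and 15 that held by fry). The list that did not hold by fry was that of the ribosomal protein genes (fry adjusted p = 0.0872).

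**Figure D2:**
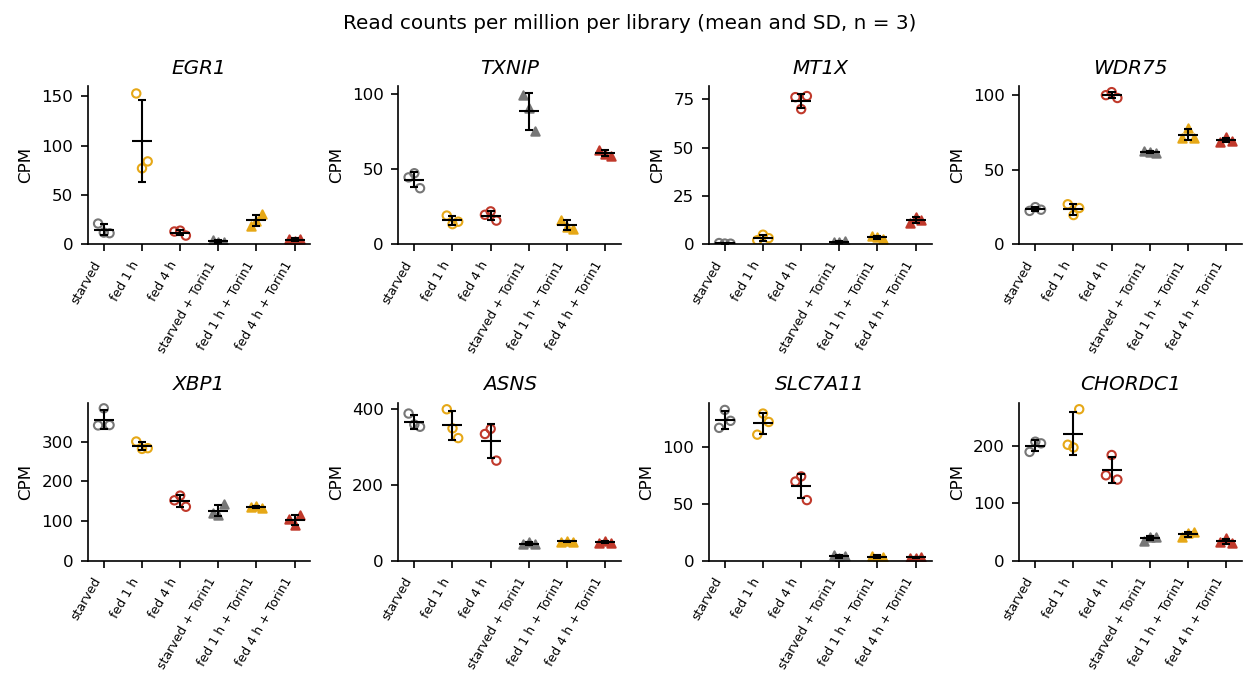
CPM of 8 named genes in each library, with the mean and SD of each group as bars (n = 3), circles without and triangles with Torin1. MT1X stood at 74.3 CPM in 4 h fed cells and 12.7 CPM with Torin1, and ASNS at 366 CPM in starved cells and 45.6 CPM with Torin1.

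Between 1 h and 4 h of feeding, EGR1 and EGR3 fell again. EGR1 was at 11.9 ± 2.68 CPM at 4 h (SD, n = 3), a log2 fold change against 1 h of −3.13 (SE 0.35, edgeR adjusted p = 7.89e-06), and EGR3 changed by −3.37 (SE 0.33). ZNF143, a transcription factor of housekeeping genes, changed by −2.69 (SE 0.15) and CHMP6, of the endosomal sorting machinery, by 4.00 (SE 0.27). TXNIP stayed low (0.27, SE 0.16, not called). In this comparison 3564 genes were higher at 4 h and 2974 lower. The 1 h and 4 h responses shared 61 higher and 20 lower genes. Independent lists of these sizes would share 18.3 and 5.16, but part of the excess may come from the starved libraries, which both comparisons use and which are too few to be split. Simulated groups without any change, the starved group included, shared 0. Since they hold no real response, they cannot show how far the starved libraries add to the overlap of real responses. The total of 81 ranged from 39 to 154 with a library left out, and 5 of 100 splits of the samples gave as many, where the other 4 kept the 4 h fed libraries together under 1 label and splits without this gave at most 8.

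Torin1 in starved cells asked what mTOR activity maintains without feeding. Genes that ATF4 induces for amino acid supply fell most clearly. The asparagine synthetase gene ASNS (ENSG00000070669) went from 366 ± 18.6 to 45.6 ± 2.95 CPM (SD, n = 3), a log2 fold change of −3.00 (SE 0.10, edgeR adjusted p = 1.6e-20), and PSAT1, of serine synthesis, changed by −2.50 (SE 0.08). The cystine transporter SLC7A11 changed by −4.89 (SE 0.19) and the glutathione-degrading CHAC1 by −5.55 (SE 0.33), down to 0.806 ± 0.472 CPM. ATF4 itself fell by 0.74 on the log2 scale. The hexokinase HK2 changed by −2.35 (SE 0.10), the glucose transporter SLC2A1 by −2.21 (SE 0.10), and CHORDC1, a cochaperone of HSP90, by −2.34 (SE 0.12). The actin regulator ARPIN rose by 4.16 (SE 0.15), from 5.37 ± 1.15 to 95.8 ± 3.05 CPM, and MYC by 0.92 (SE 0.11).

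In starved cells Torin1 raised 5559 genes and lowered 4860 (6494 and 4063 with total counts). Of 32 genes of the ATF4 and amino acid list, 29 were lower, 2 higher and 1 not called, the same counts as when adjusted over the list alone, with a median of −1.74. That list was the only 1 of 16 called here to hold with an estimated correlation (camera adjusted p = 5.5e-14; 0.0413 with an estimated correlation). The heat shock list had 15 of 18 genes lower and 0 higher, the ribosome assembly list 34 of 42 lower and 4 higher (34 and 5 when adjusted over the list alone), and the aminoacyl-tRNA synthetase list 14 of 20 lower and 5 higher, with GARS1 at −2.09 (SE 0.09). UBTF went against its list, with a rise of 1.79 (SE 0.09), as did WDR75, at 23.6 ± 1.30 CPM in starved cells and 61.9 ± 0.834 CPM with Torin1. Glycolysis genes (14 of 21 lower, 3 higher), cholesterol synthesis genes (18 of 24 lower, 3 higher) and unfolded protein response genes (14 of 18 lower, 1 higher) were also shifted down. The median of the ribosomal protein genes was −0.00, at −0.05 with DESeq2 size factors and 0.13 with total counts, so no direction can be given; 18 of 79 were higher and 10 lower (18 and 9 when adjusted over the list alone).

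In 1 h fed cells Torin1 had effects on much the same genes. STC2, a stress-induced secreted glycoprotein, changed by −2.97 (SE 0.09, edgeR adjusted p = 4.69e-21, n = 3 per group), from 317 ± 23.2 to 40.5 ± 0.758 CPM. ASNS changed by −2.79 (SE 0.10) and SLC7A11 by −5.10 (SE 0.19). EGR1 stood at 24.3 ± 5.76 CPM with Torin1 against 105 ± 41.9 without it (−2.10, SE 0.32), and the stress genes DDIT4 and SESN2, which restrain mTOR, changed by −2.83 (SE 0.31) and −1.87 (SE 0.16). TTC5 rose by 3.85 (SE 0.17) and WDR75 by 1.64 (SE 0.10). Calls were 5452 higher and 4910 lower (6228 and 4184 with total counts). Camera called 11 lists, each downward, and the ATF4 and amino acid list (29 of 32 lower, 1 higher, also when adjusted over the list alone) held with an estimated correlation, at an adjusted p of 0.0438.

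Torin1 in 4 h fed cells asked which genes differed with the inhibitor after the longer feeding. SLC7A5, the leucine transporter gene, changed by −2.82 (SE 0.10, edgeR adjusted p = 7.09e-19), from 605 ± 17.4 to 85.5 ± 4.69 CPM (SD, n = 3). The ribosome assembly gene URB2 changed by −1.87 (SE 0.10), SREBF1, a regulator of lipid synthesis, by −1.40, and the splicing factor SRSF4 by −1.24 (SE 0.08). ACTA2, smooth muscle actin, rose from 2.13 ± 0.843 to 23.0 ± 2.32 CPM (3.43, SE 0.20) and the protease gene CTSO from 0.603 ± 0.388 to 10.3 ± 1.35 CPM (4.05, SE 0.34). TXNIP rose by 1.66 (SE 0.15), and KLHL24, a FOXO target, by 0.91 (SE 0.12).

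Torin1 in 4 h fed cells gave 4505 higher and 4693 lower genes, 49.0% higher. With total counts the split was 5773 to 3453, 62.6% higher. Total counts moved the median of all genes by 0.14, 0.11 and 0.16 for Torin1 in starved, 1 h fed and 4 h fed cells, so smaller list medians rest on the scaling. Of 21 lists called by camera, 4 held with an estimated correlation: ribosome assembly (39 of 42 lower, 2 higher; adjusted p = 0.0484), ATF4 and amino acids (26 of 32 lower, 1 higher; 0.0256), tRNA synthetases (15 of 20 lower, 1 higher; 0.0256) and NRF2 targets, the antioxidant response (10 of 13 lower, 0 higher, 11 lower when adjusted over the list alone; 0.0484). The other counts were the same when adjusted over the list alone. Upward, 5 lists were called and 0 of them held. FOXO targets were higher in 12 of 22 cases and lower in 1 (14 and 1 when adjusted over the list alone), translation factors with 5′ terminal oligopyrimidine (TOP) motifs in 11 of 14 and lower in 2, and ribosomal protein genes in 33 of 79 and lower in 5 (31 and 5 when adjusted over the list alone; median 0.19, also 0.19 with DESeq2 size factors and 0.35 with total counts). The other 2 were host genes of small nucleolar RNAs with TOP motifs (8 of 13 higher, 2 lower) and SRF and actin genes (8 of 16 higher, 2 lower).

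**Figure D3:**
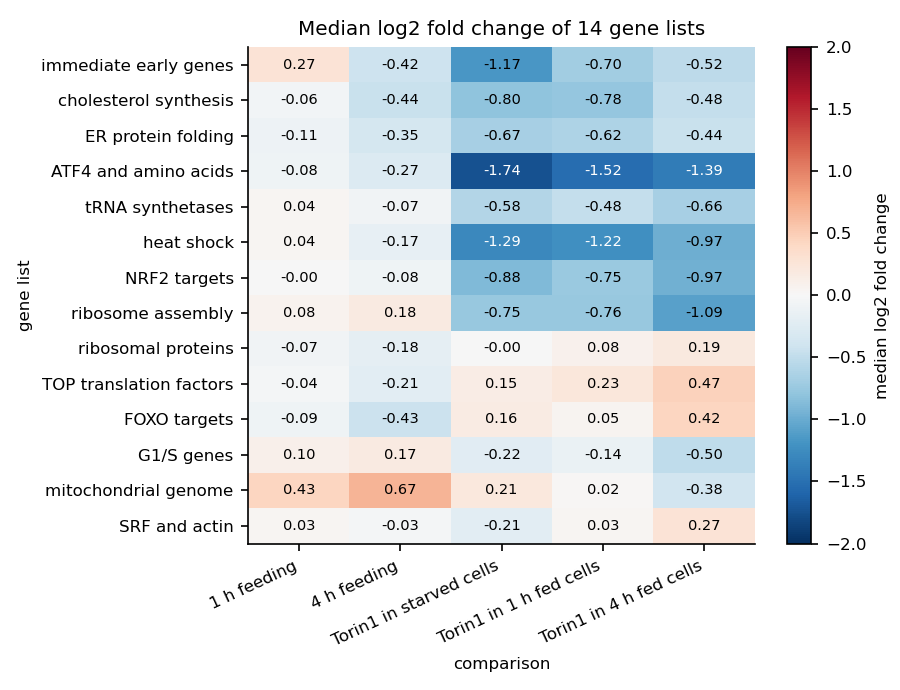
Median log2 fold change of gene lists, with red higher and blue lower. The ribosomal protein median in starved cells with Torin1 (−0.00) changed sign with total counts (0.13).

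Torin1 moved 3081 genes upward and 3210 downward in all 3 feeding states, which share no library. Independent lists would share 506.8 and 415.7. ASNS, SLC7A11, CHAC1, STC2 and PSAT1 were among the lower genes. Markers of fibroblasts and immune cells, included to look for RNA of other cells, were called by camera in 0 of the 7 comparisons with list tests (smallest camera adjusted p 0.0819 and 0.398), and those of carcinoma and endothelial cells, with 3 of 11 and 0 of 7 genes tested, were too few to test, as were metal response genes, with 4 of 7. The fibroblast list nevertheless had a median of −2.54 for 4 h feeding and 1.73 for Torin1 in 4 h fed cells, where 2 of 7 genes were higher and the fry adjusted p was 0.00339. Genes chosen after their values were seen were COL1A2, at 2.45 CPM in starved and 0 in 4 h fed cells, COL3A1, at 3.79 and 0.622, and CD14, at 1.02 and 0.326.

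Feeding in the presence of Torin1 asked which responses do not need mTOR activity. After 1 h, EGR3 rose by 4.87 (SE 0.37, edgeR adjusted p = 9.67e-10), from 0.529 ± 0.266 to 16.2 ± 6.09 CPM (SD, n = 3). FOSB rose by 3.30 (SE 0.31) and EGR1 by 2.89 (SE 0.41), though the call of EGR1 was lost without starved Torin1 replicate 2 or 3. TXNIP fell from 88.6 ± 12.3 to 12.7 ± 3.29 CPM (−2.81, SE 0.16, edgeR adjusted p = 8.81e-12), and GAS1, a growth arrest gene, changed by −1.01 (SE 0.11). After 4 h, MT1X rose by 3.26 (SE 0.24), ID1 by 2.47 (SE 0.20) and the matrix gene EMILIN2 by 2.37 (SE 0.17). The zinc importer SLC39A10 and the transferrin receptor TFRC changed by −1.40 (SE 0.17) and −1.31 (SE 0.13), and MYC by −0.85 (SE 0.11), whereas without Torin1 MYC rose by 0.43 (SE 0.11).

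With Torin1, 45 genes were higher and 21 lower at 1 h, 68.2% higher, and with total counts the split was 27 to 34, 44.3% higher. At 4 h 136 were higher and 160 lower. The 1 h count fell to 22 without starved Torin1 replicate 2 and the 4 h count to 134 without 4 h fed Torin1 replicate 2, and no library left out gave as many calls as the full data (at most 45 and 189). Other fits gave more, 119 and 491 with the DESeq2 Wald test and 208 and 640 with only the groups compared, and at 1 h 150 with no filter and 110 with a replicate block, though 40 with limma-voom. Of the 4 h calls without Torin1, 73 higher and 84 lower genes were called in the same direction with it, against 31.5 and 30.6 for independent lists. Their total of 157 fell to 76 without 4 h fed Torin1 replicate 2 and was 260 with the DESeq2 Wald test. No library was shared between these comparisons. The median log2 fold change of the 3801 higher genes was 0.75 without and 0.06 with Torin1, and that of the 3139 lower genes −0.57 and −0.05.

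The interaction asked whether feeding acted differently with Torin1. At 1 h the rise of EGR3 was larger with Torin1 by 2.86 (SE 0.49, edgeR adjusted p = 0.0112, n = 3 per group) and the fall of TXNIP larger, by −1.36 (SE 0.22, edgeR adjusted p = 0.00808). Both differences lay mainly in the starved levels. Without and with Torin1, EGR3 stood at 3.59 ± 1.07 and 0.529 ± 0.266 CPM in starved cells and 14.4 ± 2.80 and 16.2 ± 6.09 after 1 h. TXNIP stood at 43.1 ± 5.16 and 88.6 ± 12.3 CPM in starved cells and 15.9 ± 2.94 and 12.7 ± 3.29 after 1 h. The call of EGR3 was lost without starved Torin1 replicate 2 or 3 and that of TXNIP without 1 h fed Torin1 replicate 2. EGR1 did not differ detectably (0.06, SE 0.52). In all, 2 genes were called with a more positive and 9 with a more negative effect, and the count lay between 3, without starved Torin1 replicate 3 or 1 h fed Torin1 replicate 2, and 39, without 1 h fed replicate 1. At 4 h the responses of WDR75 and MRTO4 were smaller with Torin1, by −1.91 (SE 0.13) and −1.66 (SE 0.12), as was that of MT1X, by −3.98 (SE 0.45, edgeR adjusted p = 4.51e-08). MYC differed by −1.28 (SE 0.15) and FOS by 2.11 (SE 0.54). A more positive effect was called for 1599 genes and a more negative 1 for 2634. Of the 4 h calls without Torin1, 2491 of 3801 higher and 1462 of 3139 lower genes had a smaller response with Torin1 by this test. A larger response was called for 6 and 2 of them. The calls and the interaction share the starved and 4 h fed libraries without Torin1, so part of this imbalance comes from the choice of genes. Of 16 SRF and actin genes, 11 had a more positive effect and 0 a more negative (12 and 0 when adjusted over the list alone), including CNN2 (1.43, SE 0.15) and SRF (1.08, SE 0.13). This list held with an estimated correlation (camera adjusted p = 2.8e-06; 0.0374 with an estimated correlation), the only 1 of 12 called at 4 h to do so, and at 1 h 0 of 10 held.

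Feeding for 4 h and Torin1 moved many genes in the same direction. TTC5 stood at 2.76 ± 0.468 CPM in starved cells (SD, n = 3), 32.5 ± 1.33 after 4 h of feeding and 35.0 ± 2.68 in 1 h fed cells with Torin1, and WDR75 at 23.6 ± 1.30, 100.1 ± 1.97 and 73.7 ± 3.67. WDR75 does not stand for the ribosome assembly list. Of its 42 genes, 19 were higher and 5 lower at 4 h, while 4 were higher and 34 lower with Torin1 in starved cells. ZNF143 stood at 101 ± 1.67, 16.7 ± 4.43 and 20.6 ± 2.69 CPM. Sizes differed for ASNS, called lower in both, with 366 ± 18.6, 314 ± 44.8 and 51.5 ± 1.68 CPM, a log2 fold change of −0.22 (SE 0.09) for 4 h feeding and −2.79 (SE 0.10) for Torin1. Between 4 h feeding and Torin1 in 1 h fed cells, which share no library, 2466 genes were higher in both and 1986 lower in both, against 1263 and 939 for independent lists, while 415 were higher at 4 h and lower with Torin1 and 309 the reverse. The correlation of log2 fold changes was 0.43 across genes, which are not independent replicates.

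**Figure D4:**
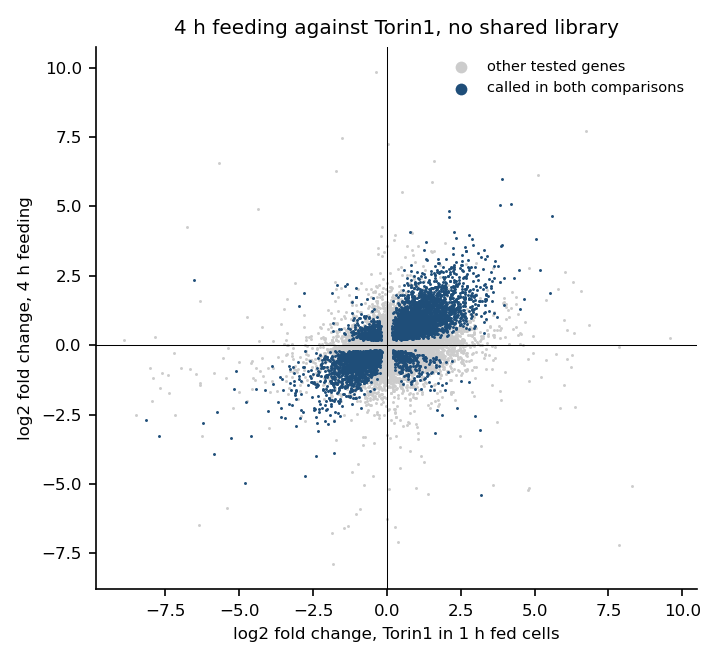
Log2 fold change of 4 h feeding against that of Torin1 in 1 h fed cells, 1 point per tested gene. Dark points are genes called in both comparisons, of which 2466 were higher in both and 1986 lower in both.

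Isoform estimates of a few genes differed between groups, but these genes were top ranks of the isoform test, which failed in simulated data. The counts are estimates that divide reads between transcripts. Other top ranks varied within a group: HNRNPAB-201 had 16 to 1166 counts in the 4 h fed libraries and TCF3-202 had 18 to 243 in the starved libraries. ATXN2L-202, of an RNA-binding protein gene of stress granules, had 0 counts in the 3 starved libraries, 249 to 682 in the 4 h fed libraries and 364 to 583 in the starved libraries with Torin1, where it held 17.1% ± 4.48 of the gene's counts (SD, n = 3). CLTC-201, of the clathrin heavy chain, went from 0 to between 419 and 1086 counts at 4 h and to between 1021 and 1759 with Torin1. RPS26-201 fell from between 633 and 743 to between 15 and 29 counts with Torin1 in starved cells, and HSPD1-201 from between 1020 and 1574 to between 0 and 93. In 4 h fed cells, RBM39-206 had 0 counts without Torin1 and 371 to 446 with it. The test called 143, 560 and 380 genes for 4 h feeding, Torin1 in starved cells and Torin1 in 4 h fed cells, and limma-voom 581, 2210 and 1971. The edgeR isoform test recovered 7 of 100 genes changed 4-fold in simulated data, so these counts are not interpreted. Between 12.1% and 13.9% of isoforms with at least 30 reads in a library of a group had under 3 in another library of it.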

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

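The tests of the interaction were planned before the data were examined, and the tests of shared control libraries, of mixed RNA and of scaling were chosen after the result was seen. Feeding effects differed with Torin1 by the interaction test of edgeR for 11 genes at 1 h and 4233 genes at 4 h, and by camera for 10 and 12 lists. At 1 h the named genes were EGR3 (2.86), SLC30A1 (1.56), ARRDC4 (−0.77), TXNIP (−1.36), KBTBD7 (−1.74) and H4C14 (−1.92), as differences of log2 fold changes. At 4 h those with a more positive effect under Torin1 were RELB (2.96), CDKN2D (2.70), DNAJB1 (2.32), CFAP418 (2.27), DDIT3 (2.24), ZNF143 (2.16), FOS (2.11), CHAC1 (1.63), PPP1R15A (1.53), TRIB3 (1.47), CNN2 (1.43), HERPUD1 (1.13), SRF (1.08), KLHL24 (0.95), XBP1 (0.94), HMGCS1 (0.74), TXNIP (0.62), GAS5 (0.48), EIF3F (0.46), EIF4B (0.38) and RPL14 (0.34). Those with a more negative effect were ZNF619 (−4.47), MT1X (−3.98), F8A1 (−3.68), KBTBD7 (−3.39), SNPH (−3.35), TTC5 (−3.34), WDR75 (−1.91), MRTO4 (−1.66), MYC (−1.28), SREBF1 (−0.92), MT-ATP8 (−0.89), CCND1 (−0.81), MT-ND6 (−0.63), RPS26 (−0.61) and SQSTM1 (−0.38). Torin1 alone lowered or raised many of these genes, so a floor or ceiling on their levels was not excluded gene by gene.

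For the 4233 genes at 4 h, 2 of 100 splits, the real split included, gave as many. The other 1, with 9713 genes, had the Torin1 labels of a whole feeding state exchanged, and splits without this gave up to 362. The splits exchange Torin1 labels, so mixed groups lose the Torin1 effect itself and gain spread. They therefore cannot exclude chance for the interaction, and the count rests on the edgeR test. Nor was it excluded for the 11 genes at 1 h, where 8 of 100 splits gave as many and the highest other gave 6925. With the Torin1 labels of a whole feeding state exchanged, the interaction adds Torin1 effects instead of subtracting them, so large counts follow. This was so in 5 of the 7 other splits, but splits without such a state still gave up to 3421 genes. Whether labels exchanged in part of a state explain these was not tested. Chance was not excluded for the lists either, with 49 of 100 splits reaching 10 lists at 1 h (highest other 16) and 53 of 100 reaching 12 lists at 4 h (highest other 23).

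The response to 4 h of feeding was smaller with Torin1. Its genes were chosen by their response without Torin1, so part of the gap may come from that choice, whose size was not tested. If the smaller response came only from genes that Torin1 alone had already moved, the other genes would have kept their response. The 2488 genes that 4 h of feeding moved and that Torin1 did not move the same way in 1 h fed cells kept 8.80% of their median log2 fold change (0.57 without and 0.05 with Torin1), which speaks against that explanation as the whole cause. Scaling does not account for it, since a scale factor shifts all genes alike, while the gap between the medians of higher and lower genes kept 8.402% of its size (1.32 without and 0.11 with Torin1). A need for mTOR activity in the 4 h response, which the design addresses, may therefore be a candidate explanation, as a hypothesis found and tested on the same data; the dose, timing and general toxicity of Torin1 were not tested.

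Feeding for 4 h and Torin1 moved genes the same way. Shared starved libraries are not the cause, since 86.0% of genes called both for 4 h feeding and for Torin1 in 1 h fed cells, with no library in common, moved in 1 direction. A bias by transcript length and GC content, known for 99.0% of tested genes, is not the cause either, since 85.6% did so after a trend on both was removed.

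RNA of Torin1-treated cells mixed at a single share into the 4 h fed libraries, with no response to feeding beside it, did not give the levels seen. Of 424 genes that Torin1 moved at least 4-fold in 1 h fed cells, 47.9% (exact interval 43.0% to 52.8%) lay over 2 SE from the best mixture, past the bound of 20 percent. Genes it lowered would need a median share of 57.1% against 29.8% for those it raised. A response to feeding would also move genes off the mixture, so this misfit cannot exclude mixed RNA as the source of the shared direction. MT1X, at 74.3 CPM in 4 h fed cells and at most 12.7 CPM with Torin1, lay above what a mixture of the other groups could give. It was not called for Torin1 in 1 h fed cells (0.03, SE 0.24), so it does not bear on the shared direction. A limit on the share holds whatever feeding did to a gene. A share of 31.2%, needed by the genes lower in both, would bring each gene to a level that 17 of 11696 genes lay below. These 17 genes argue against a share that large. Their number lay between the bounds of 5 and 20 set for this test, and a form of it with overstated errors had given 0. Such RNA at a smaller share, as a part of the cause, stays open. ACTA2, CTSO and WDR31 were among the 17 and allow a share of at most 9.90%, 6.90% and 5.34% by their means, and a biological overlap between feeding for 4 h and loss of mTOR activity was not tested.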

How the results depend on the processing

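Scaling by total counts was added after the data were seen, and the other alternatives were planned. Of 424 values of 171 named genes, 282 of them called, 0 reversed under an alternative, nor did a called list. For isoform genes only the p of the gene was compared, so a reversal could not be seen. Counts stayed within 1.5 times with DESeq2 size factors, a mean of at least 1 CPM, mitochondrially encoded genes left out and total counts, apart from the splits given with the results. The DESeq2 Wald test gave 173 genes for 1 h feeding, 119 and 491 for 1 h and 4 h feeding under Torin1, 43 for the interaction at 1 h, 129 shared by 1 h and 4 h feeding and 260 that held under Torin1. Limma-voom gave 40 genes for 1 h feeding under Torin1 and 7 for the interaction at 1 h. With no filter, 1 h feeding gave 164, 1 h feeding under Torin1 150 and the interaction at 1 h 77. Fits of only the groups compared gave 39 for 1 h feeding, 208 and 640 for 1 h and 4 h feeding under Torin1 and 4 for the interaction at 1 h. An estimated correlation left 0 lists for 1 h feeding, 4 h feeding and the interaction at 1 h, 1 each for Torin1 in starved and 1 h fed cells and the interaction at 4 h, and 4 for Torin1 in 4 h fed cells. Fry called 1 list for 1 h feeding and for the interaction at 1 h, and 27, 28 and 32 for Torin1 in starved, 1 h fed and 4 h fed cells. It asks another question, without comparing a list with other genes. For the gene tests the cause was not tested. Unfiltered fits test more genes and fits of the groups compared use fewer samples, but whether either moved the counts is not known. Isoforms holding at least 10% of their gene gave 52, 262 and 131 genes for 4 h feeding, Torin1 in starved and Torin1 in 4 h fed cells, and limma-voom 581, 2210 and 1971; the cause was not tested.

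With replicate number as a block, 1 h feeding under Torin1 gave 110 genes and the interaction at 1 h 23, and 21 of 23 counts stayed within 1.5 times. The numbers are not taken to pair the samples: correlations of deviations of same-numbered libraries ranged from −0.11 to 0.16, and in no comparison were all above 0.1. Even so, 13 of 18 libraries lay closest to their own number, against a mean of 6.72 for numbers drawn anew within groups, where 2 of 100 draws gave as many, a hint from the data of an effect shared by number.

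Leaving out each library gave 55 to 248 genes for 1 h feeding, 22 to 45 and 134 to 189 for 1 h and 4 h feeding under Torin1, 3 to 39 for the interaction at 1 h, 7 to 16 lists for 1 h feeding (7 without 1 h fed replicate 3), 85 to 122, 299 to 379 and 200 to 273 genes with changed isoform use for 4 h feeding, Torin1 in starved and Torin1 in 4 h fed cells, 39 to 154 genes shared by 1 h and 4 h feeding (39 without 1 h fed replicate 2, 154 without 1 h fed replicate 1) and 76 to 152 that held under Torin1 (76 without 4 h fed Torin1 replicate 2). Fewer samples lower most of these counts. Of 3054 values of named genes with a library left out, 121 lost the threshold, 22 passed it and 0 reversed. Depth limits genes near 0.285 CPM, such as MT1F in starved cells.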

Other observations

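Metal-handling genes were singled out after their values were seen. MT1X was already higher after 1 h of feeding, by 2.82 (SE 0.36, edgeR adjusted p = 4.42e-05), whereas MT2A and MT1F were not called. After 1 h of feeding under Torin1, MT1X (1.43, SE 0.28), MT2A (0.82, SE 0.17) and MT1F (1.65, SE 0.38) were called higher. With 4 h of feeding the zinc exporter gene SLC30A1 rose by 1.71 on the log2 scale (SE 0.14, edgeR adjusted p = 1.57e-09) along with MT1X, MT2A and MT1F. The zinc importer SLC39A10 fell from 284 ± 40.6 to 89.9 ± 19.0 CPM (SD, n = 3) and the transferrin receptor TFRC from 707 ± 79.3 to 269 ± 18.2 CPM. With Torin1 these genes moved in the same directions at 4 h: SLC30A1 by 1.76 (SE 0.16), SLC39A10 by −1.40 (SE 0.17) and TFRC by −1.31 (SE 0.13), and the interaction at 4 h was not called for SLC30A1 (0.05, SE 0.21), SLC39A10 (0.26, SE 0.24) or TFRC (0.09, SE 0.18). It was called for MT2A (−2.36, SE 0.24) and MT1F (−2.07, SE 0.62). Metal levels of the media were not analysed here.

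Other splits of the same 6 samples are too few (10) for a share under 0.05. As many genes as in the real split came from 1 of 10 splits, the real split itself, for 1 h feeding (106, highest other 72), 4 h feeding (6940, 0), 4 h against 1 h (6538, 1), Torin1 in starved, 1 h fed and 4 h fed cells (10419, 10362 and 9198, each with 0), and feeding under Torin1 at 1 h (66, 1) and 4 h (296, 0). Lists as many as the real count came from 2 of 10 splits for 1 h feeding (15, highest other 16), 1 for 4 h feeding (16, 11), 2 for Torin1 in starved cells (16, 17), 6 for Torin1 in 1 h fed cells (11, 12) and 1 for Torin1 in 4 h fed cells (21, 18), so with the preset correlation mixed groups reached or passed the real count in 3 of 5 comparisons. Isoform calls came from 1 of 10 splits in each case (143, 560 and 380, highest others 55, 32 and 30). Of 100 drawn splits, 1 gave as many genes moved by Torin1 in all 3 feeding states (6291, highest other 0). As many 4 h calls that held under Torin1 came from 1 as well (157, highest other 1). So chance was excluded for an effect of Torin1 and of 4 h of feeding as such, if the libraries count as separate samples, which the labels do not say. It was not excluded for 1 h of feeding, nor for the overlap of lists that hold real effects. For genes shared by 1 h and 4 h feeding chance was not excluded by this count alone, with 5 of 100 (81, highest other 5243). All 4 of the other splits kept the 4 h fed libraries together under 1 label, and so kept their difference from the other libraries. Splits without this gave at most 8.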
